A study of Homo sapiens with 2 samples.

How the data were processed

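Total RNA of HEK293 cells, a line derived from human embryonic kidney, was sequenced in parental cells and in LARP7 knockout clone 1-11, with 2 libraries per group. Per the labels, RNA was extracted with TRIzol and libraries were made with the Ovation SoLo kit. One field of the knockout sample calls it wildtype, while its title and genotype field call it a knockout, and the genotype field was used. Nothing states whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All knockout libraries come from 1 clone, so any other difference between that clone and the parental cells is confounded with the knockout.

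The deposited tables give, per transcript, estimated counts (reads assigned by Salmon, not whole numbers), TPM (transcript abundance scaled to a fixed total) and effective length. The authors' estimated counts and TPM are named in the table headers, and the tools named per the submitters' processing notes were cutadapt 1.6, STAR 2.5.3a, SAMtools 1.3.1, Picard, Salmon 1.6, R 3.3.3 and 3.5.1 and edgeR 3.24.3, with genome build hg38; which of them produced which value, the annotation release and the strand setting are not given in the sources used here. The effective length in the deposited tables is the transcript length corrected for fragment length, and it was used only for the transcript-length offset and to compare fragment length between libraries. Salmon divides reads among similar transcripts, which adds an assignment error that the tests below do not see.

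Transcript identifiers were joined to GENCODE v29 (GRCh38): 197318 of 198002 transcripts matched and 684 did not, and the latter held 0.063 to 0.071% of the reads. Estimated counts were summed per gene and rounded to whole numbers. The 4 libraries held 18483220, 12851942, 16838501 and 16218587 estimated reads. The 7SK gene has 2 entries at the same locus; the reads lie on the second, and this entry was chosen after its values were seen.

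Genes were tested with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F test, knockout minus parental, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The standard error is the log2 fold change divided by the root of F. Levels are CPM, counts scaled to a common library size with the TMM factors. The gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except for the windows of neighbouring genes, the small RNA families and the tests of the closing section. Lists were tested with camera at a preset correlation of 0.01, with limma 3.58.1; members were also adjusted over the list alone. Transcript usage was tested with diffSpliceDGE and gene-level Simes p, over transcripts with at least 10 reads in 2 libraries and at least 5% of their gene in 2 libraries. Shares of retained-intron and nonsense-mediated-decay transcripts in protein-coding genes came from TPM and were compared with a two-sided exact permutation test, which cannot go below p = 0.333 with 2 against 2 libraries. Windows of 60 protein-coding genes with an average log2 CPM above 3, in steps of 10 genes, were compared with 1000 shuffles of the gene order, and overlapping windows beyond the highest shuffled median were merged into regions. Lists with at least 5 genes tested for usage were compared with Fisher's exact test, two-sided.

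Genes were named by this rule: LARP7 and the 7SK list, the 10 largest rises and 10 largest falls and the 5 smallest p in each direction (adjusted p under 0.05, average log2 CPM of at least 2, groups not overlapping, protein coding or lncRNA with a proper symbol), up to 4 members per list, members of the 7SK and splicing-factor lists with changed usage, and the 10 largest usage shifts with at least 100 reads of the gene in every library. Of the genes it selects, 1 is not reported here. Genes named outside it are said to be chosen after their values were seen. A fold against a group at 0 was computed against a floor of 3 counts per library, which covers counting error only.

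The alternatives were DESeq2 1.42.0, limma voom, other scaling factors, library size alone, other filters, an offset for transcript length, protein-coding genes only, a replicate block and each library left out in turn; for usage, other tests, share minimums and count minimums; for lists, an estimated correlation and fry. With 4 libraries, an estimated correlation leaves camera few degrees of freedom. A call lost there does not show that correlation between members caused it. For the epithelial and mesenchymal list the estimate was -0.007, below the preset 0.01, yet the camera adjusted p went from 0.0521 to 0.737. The steps were tested on simulated data. In 10 simulations with 200 changed genes, drawn from the fitted gene-specific dispersions, edgeR called on average 46.8% of genes changed 2-fold and 78% of those changed 4-fold, and 9.63% of its calls were unchanged genes (2.52 to 17.6%), above the nominal 5%; with dispersions that followed the trend, that share was 3.9%. DESeq2 and voom gave 8.98 and 9.29% with gene-specific dispersions. The calls of the real comparison carry the same limit. When a library is left out, its group has 1 library, which is assumed to vary like the other group.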

Results

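The transcriptome of HEK293 cells lacking LARP7, a La-related protein that binds and stabilises 7SK RNA, was compared with that of the parental cells, to measure its effect on expression and splicing. Total RNA was sequenced in 2 parental and 2 knockout libraries. The libraries held 18483220 and 12851942 estimated reads in parental cells and 16838501 and 16218587 in the knockout. Parental replicate 2 stood apart from replicate 1: it was shallower, had shorter fragments by effective length (206.7 against 217.0 bases) and a larger share of reads from small RNA genes (2.36 against 1.41%). Both knockout libraries had longer fragments by the same measure (232.9 and 225.8 bases) than both parental libraries. Their share of reads from small RNA genes, 7SK included, was smaller (0.83 and 0.98%). 7SK alone held 98057 and 69038 reads in the parental libraries and 2904 and 3457 in the knockout. The smaller share therefore does not by itself show a lower recovery of other small RNAs. Counts of the parental pair differed by a chi-square of 34.75 per degree of freedom over 15429 genes, and those of the knockout pair by 9.61 over 15742 genes, so no pair agreed within sampling noise.

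LARP7 itself (chromosome 4, 112636964 to 112657592, GRCh38) had a normalised read count of 53.2 ± 9.41 CPM in parental cells and 34 ± 2.96 in the knockout (SD, n = 2), and was lower in both knockout libraries. Its log2 fold change of -0.65 (SE 0.16) did not pass the test over all genes (edgeR adjusted p = 0.135). It did pass without parental replicate 1 (-0.46, adjusted p = 0.048), without parental replicate 2 (-0.82, adjusted p = 9.59e-06), with DESeq2 (adjusted p = 0.045) and with no filter (adjusted p = 0.0119). It did not pass without knockout replicate 1 or 2 (-0.74 and -0.56, adjusted p = 0.366 and 0.687) or with an offset for transcript length (-0.46, adjusted p = 0.35). Nor did it pass with limma voom, other scaling factors, library size alone, the stricter filter or protein-coding genes only (adjusted p = 0.0766 to 0.142). Without a parental library the spread comes from the knockout pair alone. Its exons overlap those of ZGRF1 on the opposite strand. The nonsense-mediated-decay transcript LARP7-211 held 15.9 ± 0.491% of the gene's TPM in parental cells and 37.9 ± 10.6% in the knockout, while LARP7-201 held 20.2 ± 2.94% and 7.07 ± 4.3%; the usage of the gene's transcripts did not pass the test (edgeR adjusted p = 1).

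7SK RNA, the non-coding RNA that holds the elongation factor P-TEFb inactive, fell 29.6-fold. RN7SK (chromosome 6, 52995620 to 52995950) went from 5526 ± 63.9 to 187 ± 24.8 CPM (SD, n = 2; log2 fold change -4.89, SE 0.12, edgeR adjusted p = 1.13e-06), the smallest p of all 18484 genes tested. Annotated 7SK copies were lower too, with a sum over loci of 92.3 ± 28 in parental cells and 9.85 ± 1.88 in the knockout, and they can share reads with 7SK. Fragments by effective length were longer in both knockout libraries (232.9 and 225.8 bases) than in both parental ones (217.0 and 206.7). Of the 8 members of the 7SK and P-TEFb list, 1 fell and 7 did not pass over all genes with edgeR (3 passed with DESeq2, 1 with limma voom). HEXIM1, an inhibitor of P-TEFb, was at 28.9 ± 8.36 and 48.9 ± 8.5, CDK9 at 24.6 ± 2.9 and 18.4 ± 0.0112, and MEPCE, the 7SK capping enzyme, at 34.8 ± 11 and 43.3 ± 5.9 CPM. The cyclins CCNT1 (log2 fold change -0.02) and CCNT2 (-0.03) and HEXIM2 (0.13, SE 0.48) lay near 0, and both cyclins turned positive with library size alone, as did CCNT2 with an offset for transcript length (0.28). Adjusted over the list alone, RN7SK and LARP7 were lower and HEXIM1 was higher. The list passed camera (adjusted p = 3.1e-05) although its median was -0.03 and its mean -0.60; with an estimated correlation the adjusted p = 0.737. The list also lost the call with limma voom (adjusted p = 0.0966), with protein-coding genes only (0.821), where 7SK is left out, and without knockout replicate 2 (0.0632).

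**Figure D1:**
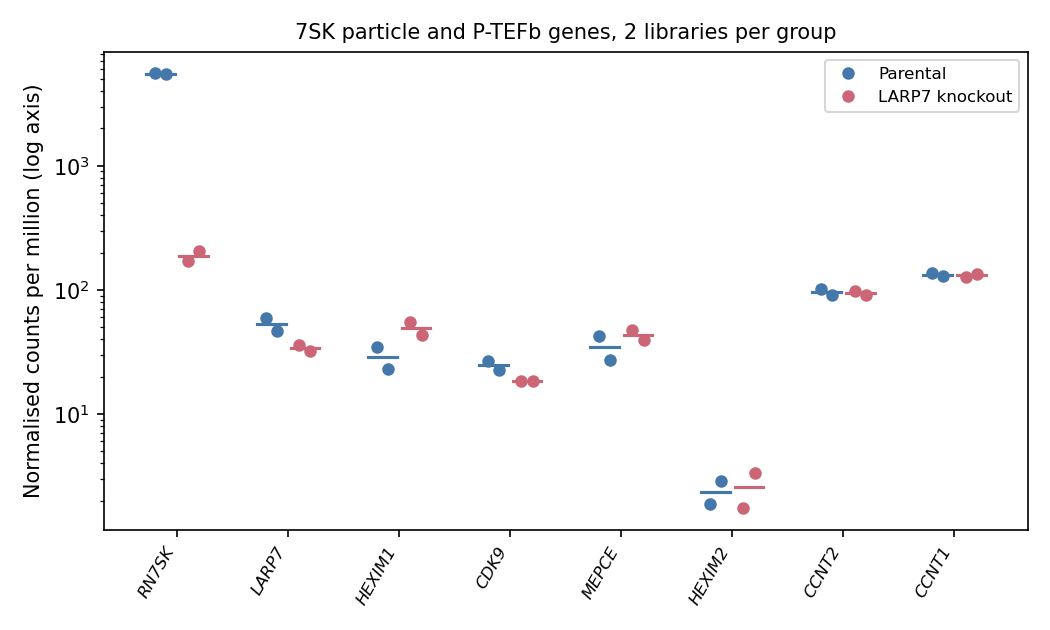
Normalised read counts in CPM (log axis) of the 8 genes of the 7SK and P-TEFb list; each point is a library and each bar a group mean. RN7SK lies at 5526 in parental and 187 in knockout cells, while CCNT1 and CCNT2 lie close together in both groups.

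Across the transcriptome, 61 genes rose and 93 fell in the knockout, 54 and 60 of them at least 2-fold. The largest rises among genes named by the rule included NELL1 (18.9-fold), FAT3, an atypical cadherin (14.3-fold), B3GALT1 (11.1-fold), AFF2 (7.98-fold), SLC16A7, a monocarboxylate transporter (7.05-fold), SELENBP1 (7.01-fold), HAS2, a hyaluronan synthase (5.63-fold), ZNF462 (5.14-fold) and SLC8A1, a sodium-calcium exchanger (4.59-fold). FAT3 (chromosome 11, 92352096 to 92896470) went from 5.2 ± 1.41 to 73.5 ± 4.7 CPM (SD, n = 2; log2 fold change 3.84, SE 0.20, edgeR adjusted p = 0.000243). SYT14, a synaptotagmin, rose 3.74-fold with a spread of 0.274 in parental cells and 1.01 in the knockout.

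Among the genes that fell, the histone gene HIST1H3F had 9.92 ± 1.23 CPM in parental cells and no reads in the knockout, which is at least 56.3-fold lower against a floor of 3 counts per library. SFT2D3, which overlaps WDR33 on the opposite strand, went from 15.2 ± 12.2 to 0, at least 86.2-fold lower; the bound was 37.4-fold without parental replicate 2 and 135-fold without parental replicate 1. The long non-coding RNA NEAT1, the scaffold of paraspeckles, fell 14.4-fold from 91.6 ± 49.5 to 6.35 ± 0.188. MIR34AHG, the host gene of the microRNA miR-34a, went from 8.15 ± 4.3 to 0.0296 ± 0.0418. ADGRL3, an adhesion receptor (chromosome 4, 61201258 to 62078335), fell 21.4-fold, TSC22D3 11.7-fold, the neurofilament gene NEFM 7.51-fold, ZNF426 5.57-fold, the cystine transporter gene SLC7A11 3.75-fold and NPTX1 3.18-fold. RMRP, the RNA of RNase MRP, was chosen after its values were seen and fell from 5688 ± 205 to 3339 ± 216.

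The balance of rises and falls depended on the scaling, since library size alone, with a median log2 change of all genes of 0.095 against 0.002 with TMM factors, gave 106 genes higher and 82 lower. Without parental replicate 1 or 2 the count was 2265 or 1825, against 208 and 200 without knockout replicate 1 or 2 (720, 501, 189 and 186 at least 2-fold, in the same order). Without parental replicate 2 the log2 change of NEAT1 was -3.16 against -3.85, of TSC22D3 -2.44 against -3.55, of SLC16A7 3.54 against 2.82 and of SELENBP1 3.55 against 2.81. TSC22D3 was at -4.18 without parental replicate 1 and ZNF426 at -3.07 without knockout replicate 1, against -2.48. SFT2D3, TSC22D3 and ZNF426 lost the call with limma voom (adjusted p = 0.0902, 0.09 and 0.0535), and NPTX1, SELENBP1 and ZNF426 with an offset for transcript length (edgeR adjusted p = 0.146, 0.148 and 0.197), while ADGRL3 moved to -5.23 from -4.42 and AFF2 to 3.67 from 2.997 with that offset.

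**Figure D2:**
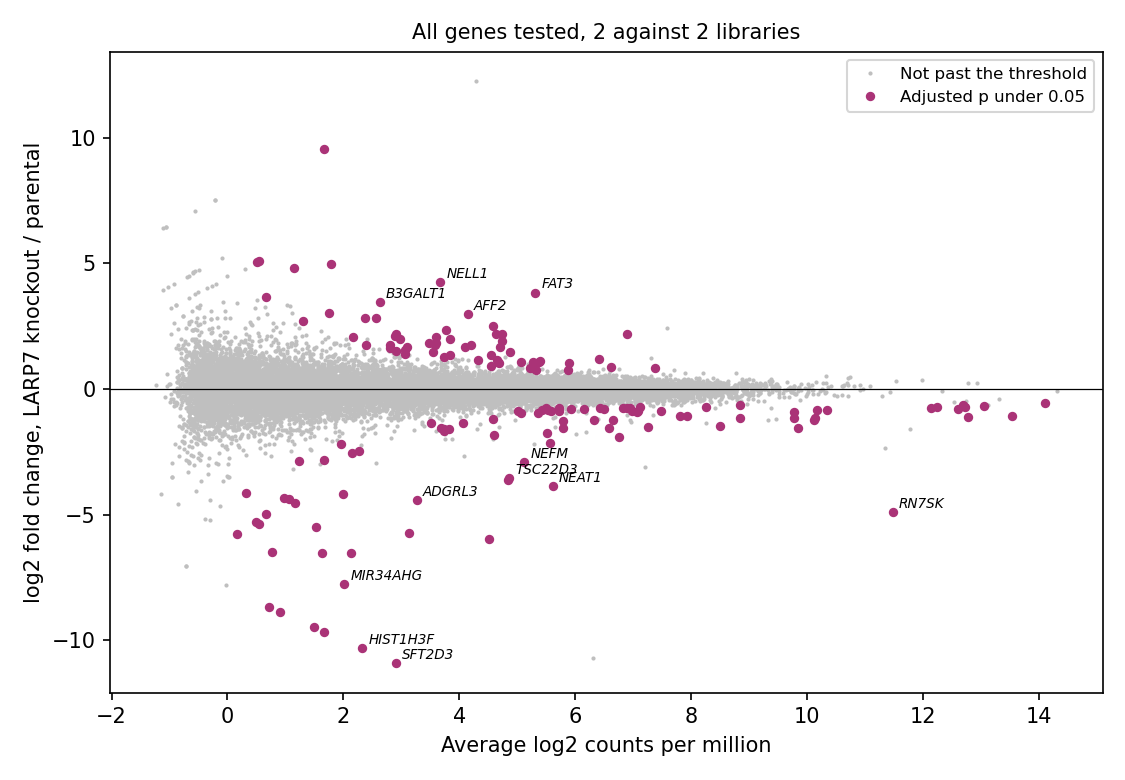
Log2 fold change of knockout against parental cells (vertical axis) against the average log2 CPM (horizontal axis) for 18484 genes; coloured points are the 61 genes that rose and 93 that fell. RN7SK lies at -4.89 among abundant genes, and the height of genes with no reads in a group, such as HIST1H3F and SFT2D3, depends on the prior count.

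All 13 mitochondrially encoded mRNAs were lower in the knockout, and 11 of them fell past the threshold over all genes with edgeR (12 passed with DESeq2, 11 with limma voom). They took 10.2 ± 0.27% of the reads in parental cells and 6.5 ± 0.51% in the knockout (SD, n = 2), whose fragments were longer by effective length (232.9 and 225.8 against 217.0 and 206.7 bases). MT-ATP6 fell 2.13-fold, from 9516 ± 374 to 4458 ± 481 CPM (edgeR adjusted p = 0.00206), and MT-ATP8, whose exon overlaps that of MT-ATP6, fell 2.74-fold. MT-ND4 went from 16080 to 7638 and MT-CO3 from 10520 to 6561. MT-ND1 (log2 fold change -0.48) and MT-ND2 (-0.64) did not pass over all genes, and all 13 passed adjusted over the list alone. The list's median was -0.78 (camera adjusted p = 1.57e-20, and adjusted p = 0.737 with an estimated correlation). Other mitochondrial RNAs were chosen after their values were seen. The rRNAs MT-RNR1 (log2 fold change -0.50, edgeR adjusted p = 0.0855) and MT-RNR2 (-0.38, 0.149) were lower and did not pass. Mitochondrial tRNAs, summed and not tested, were at 42 and 162 CPM in the parental libraries and 23.9 and 22.1 in the knockout. Nuclear genes of oxidative phosphorylation had a median of -0.002, and 0 of the 33 tested passed (4 at an unadjusted p under 0.05, 0 with DESeq2 and with limma voom).

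Genes of the unfolded protein and amino acid stress response passed camera downward at the preset correlation. The list pools unfolded protein genes with amino acid genes, which were not tested apart. The 4 members that fell over all genes, named below, are of the amino acid part. The list's call was lost with an estimated correlation of 0.06, where 4 libraries leave few degrees of freedom and no list passed. It was also lost with the directional fry test (fry adjusted p = 0.272). Log2 changes were negative in 19 members and positive in 7. Of 26 members, 4 fell over all genes with edgeR and 22 did not pass (8 passed with DESeq2, 4 with limma voom). Adjusted over the list alone, 11 were lower. The list's median was -0.48 (camera adjusted p = 2.48e-07, and adjusted p = 0.737 with an estimated correlation). SLC7A11 went from 170 ± 75.2 to 45.4 ± 3.8, the asparagine synthetase gene ASNS from 228 ± 92.7 to 79.2 ± 3.6, the serine synthesis gene PSAT1 from 332 ± 97.3 to 156 ± 12.8 and SHMT2 from 174 ± 25.7 to 95.7 ± 0.425 CPM. The parental libraries were far apart for this group: SLC7A11 was at 117.2 and 223.6 CPM and ASNS at 162.6 and 293.8 in replicates 1 and 2. SHMT2 and PSAT1 lost the call with an offset for transcript length (edgeR adjusted p = 0.0694 and 0.0613), PSAT1 also with library size alone (0.0592), and SHMT2 also without knockout replicate 1 or 2 (0.07 and 0.0677).

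**Figure D3:**
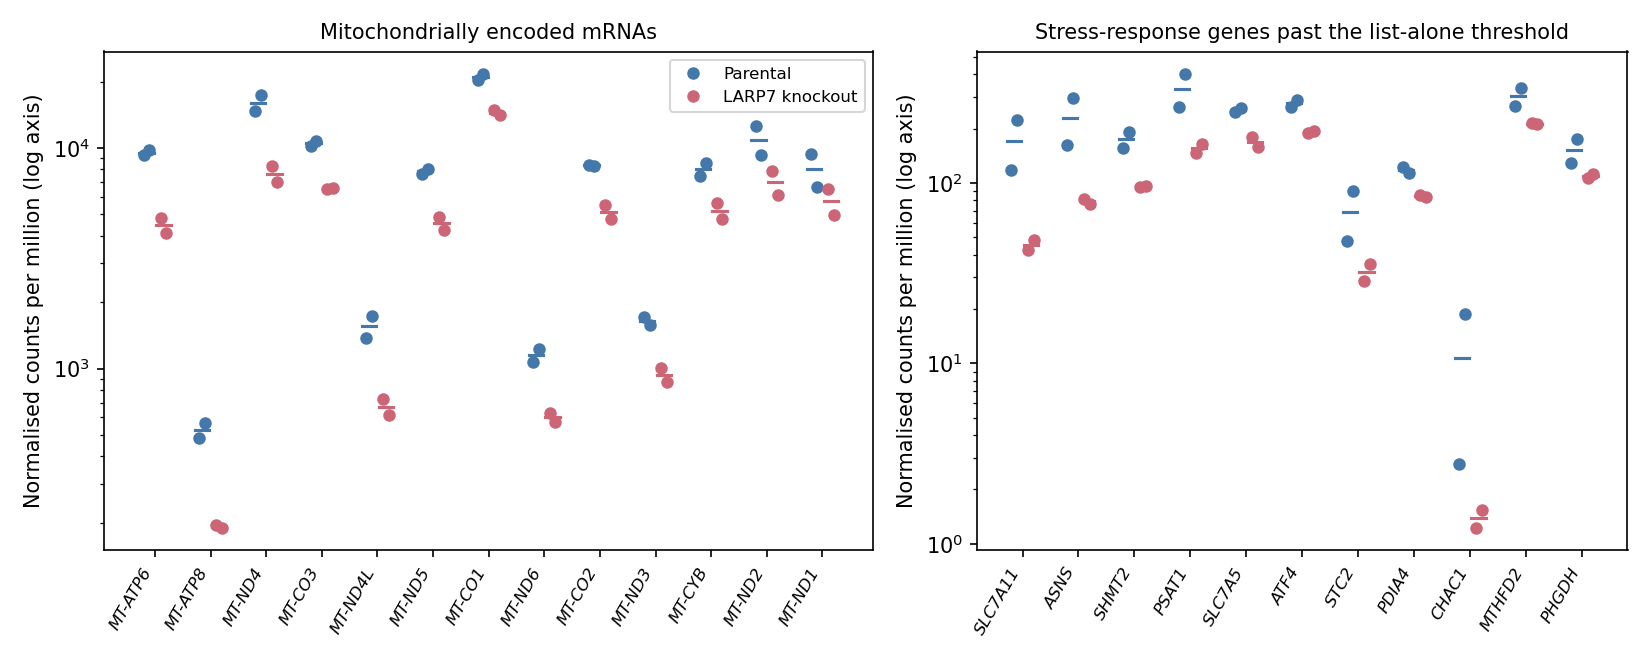
Normalised read counts in CPM (log axis) of the 13 mitochondrially encoded mRNAs and of the 11 stress-response genes lower adjusted over the list alone; points are libraries and bars group means. Every plotted gene has a lower mean in the knockout, and the parental libraries lie far apart for SLC7A11 and ASNS.

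Further lists passed camera with few members past the threshold. For the interferon response, 21 of 33 members were tested. The others had few or no reads: MX1, OAS1, OASL and IFI44 had 0 CPM in all 4 libraries, and ISG15 had 0.23 to 0.65. Of the 21, 0 passed over all genes with edgeR (8 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma voom). Adjusted over the list alone, 6 were higher. The median of the tested members was 0.51 (camera adjusted p = 4.49e-05, and adjusted p = 0.753 with an estimated correlation). HLA-B, whose exons overlap those of HLA-C, was at 50.1 ± 3.4 and 76.2 ± 5.89 and B2M at 95.8 ± 7 and 137 ± 3.56. For cell division genes, 0 of 26 passed over all genes with edgeR and 0 over the list alone (8 at an unadjusted p under 0.05, 0 with DESeq2 and with limma voom), with 22 above 0 and a median of 0.26 (camera adjusted p = 0.00144, 0.864 with an estimated correlation, and 0.11 without parental replicate 2). Of 22 Wnt and TGF-beta targets, ID3, an inhibitor of basic helix-loop-helix factors, rose from 25 ± 4.41 to 52.6 ± 3.36 and 21 did not pass with edgeR (2 passed with DESeq2, 1 with limma voom). Over the list alone, 2 were higher and 1 lower, and the median was 0.34 (camera adjusted p = 0.00144, and adjusted p = 0.737 with an estimated correlation). Of 32 replication-dependent histone genes, HIST1H3F fell and 31 did not pass with edgeR (3 passed with DESeq2, 1 with limma voom). Over the list alone 3 were lower, and the median was -0.10 (camera adjusted p = 0.0117, 0.918 with an estimated correlation, 0.216 with an offset for transcript length, 0.728 without parental replicate 1 and 0.323 without knockout replicate 2). The median turned to 0.03 without parental replicate 1. The medians of the histone and interferon lists were the same with their genes without reads in a group, 1 in each list, set to the floor. HIST1H3F, HIST1H1D, HIST1H4D and HIST1H1E lie in a region of chromosome 6 in which neighbouring genes were lower together (median -0.20). The shift of the list was not tested apart from that of the region.

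The remaining 20 lists did not pass camera. Apart from NEFM none of their members passed over all genes with edgeR or limma voom, while DESeq2 called 0 to 2 members per list. Their medians ranged from -0.105 for p53 targets to 0.31 for neuronal and neurofilament genes, of which NEFM fell and 17 did not pass with edgeR (2 passed with DESeq2). Epithelial and mesenchymal markers had a median of 0.23 (camera adjusted p = 0.0521). This list was under the threshold with DESeq2, limma voom, library size alone, no filter and the stricter filter (camera adjusted p at most 0.0448). It pools markers of opposite states, so its direction shows no shift toward either state. Extracellular matrix genes had a median of -0.005 with a mean of 0.03. Among processing factors, the medians were 0.05 for SR proteins and hnRNPs, 0.01 (mean -0.01) for U6 maturation and C/D snoRNP factors, -0.03 for the U4/U6.U5 tri-snRNP, 0.06 for telomerase and shelterin, -0.04 for the other LARP and La family genes, -0.002 for elongation and pausing factors and -0.10 for snoRNA host genes. DNA replication genes had a median of -0.06, immediate early genes 0.07, heat shock genes 0.01 with a mean of -0.05, hypoxia and glycolysis genes -0.06, cholesterol synthesis genes -0.04, cytosolic ribosomal protein genes 0.08, kidney lineage genes 0.22 and markers of other cell types 0.23, with 6 of the latter measured. Adjusted over the list alone, 1 SR protein or hnRNP gene, 1 extracellular matrix gene, 3 neuronal and 2 kidney lineage genes were higher, and 2 p53 targets, 2 extracellular matrix genes, 2 neuronal genes and 1 kidney lineage gene were lower. The heat shock list passed in opposite directions without parental replicate 1 (median 0.30, camera adjusted p = 0.000989) and without parental replicate 2 (-0.24, 0.0014). SR proteins and hnRNPs passed upward without parental replicate 1 (0.0233). Without parental replicate 2 the tri-snRNP (0.0244), DNA replication (0.00142) and cholesterol synthesis (0.0136) lists passed downward and the neuronal list (0.0378) upward.

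Genes that lie next to each other shifted together in 7 regions, in an analysis of sliding windows chosen after the data were seen. On chromosome 3, from 3126916 to 119420714, 340 expressed protein-coding genes had a median log2 change of -0.28 relative to all such genes, and TTLL3, VHL, NUP210, MRPS25, MAP4 and SUCLG2 there fell. The medians were -0.20 on chromosome 6 (291630 to 31357188), -0.37 on chromosome 7 (128297685 to 156973182), -0.29 on chromosome 8 (86342738 to 144525178), -0.14 on chromosome 18 (12307669 to 50288304), where the parental replicates differed by 0.11, -0.24 on chromosome 21 (5079294 to 46323875) and 0.19 on chromosome 10 (17142254 to 49539538). Of the genes called in the other regions, PABPC1, AZIN1 and MFSD3 (chromosome 8), ELOVL2 (6), TCAF1 and XRCC2 (7), RPRD1A and ELP2 (18) and CBS (21) fell, while HAS2, RUNX1T1 and MMP16 (8) and PLXDC2 (10) rose. Genes in this paragraph other than HAS2 were chosen after their values were seen. The chromosome 10 region rested on windows with medians of 0.192 and 0.194, only just beyond the highest shuffled median of 0.192. The regions held 10% of the genes and 19 of the 77 changed genes that entered the windows, and the knockout came from 1 clone.

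**Figure D4:**
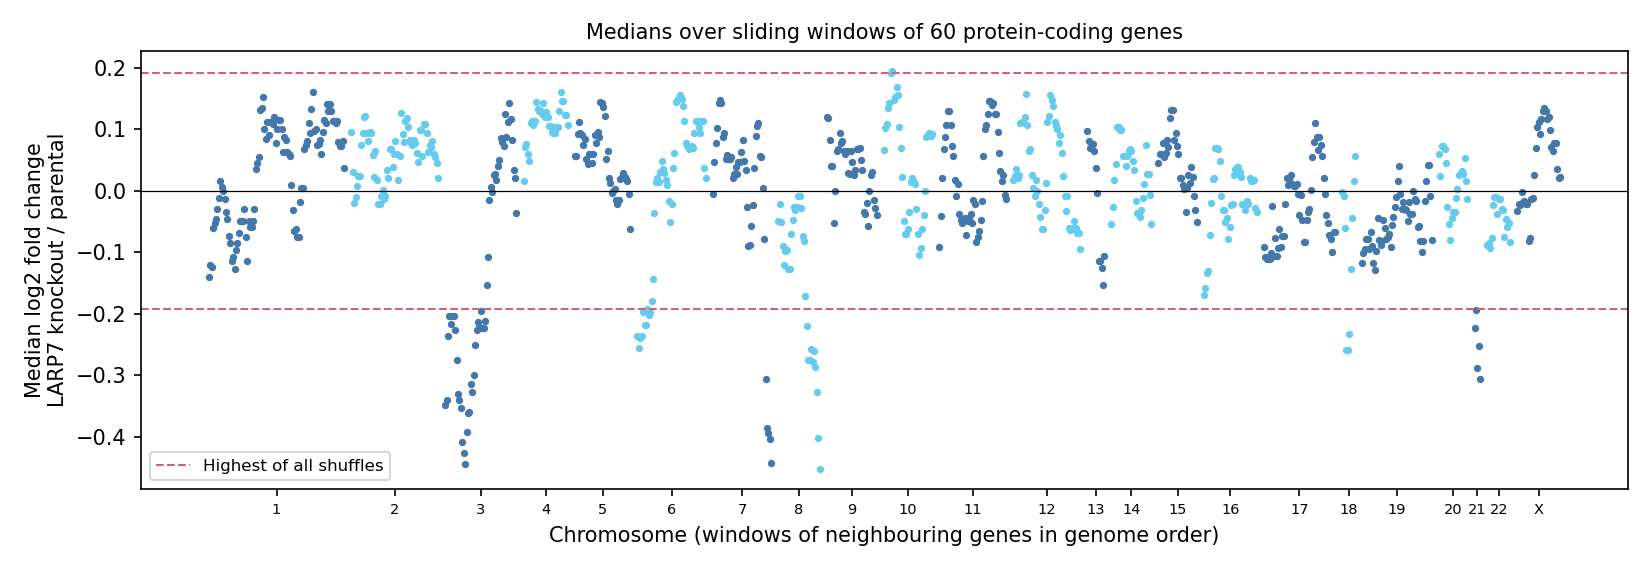
Median log2 fold change over sliding windows of 60 expressed protein-coding genes in genome order (horizontal axis, chromosomes 1 to 22 and X); dashed lines mark 0.192, the highest absolute median in 1000 shuffles of the gene order. Windows on chromosomes 3, 6, 7, 8, 18 and 21 lie below the lower line.

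Transcript usage changed in 65 of 9475 genes by diffSpliceDGE, and in 47 of them a transcript share moved by at least 10 points without overlap. In 34 of these 47, a moved transcript had no reads in either library of a group, as estimated by Salmon. The largest shifts were in NHS, where NHS-202 went from 0 to 64.6 ± 18.9% of the gene's TPM, ZNF112 (ZNF112-201, 0 to 53.4 ± 8.36%), NEFM (NEFM-204, 0.0241 to 49.4 ± 23.1%), POMGNT2, KAT14, LZTS3, ZNF81, RAD9A, HIPK3 and OSGIN2. HIPK3, a homeodomain-interacting kinase, had reads of both transcripts in all libraries: HIPK3-201 went from 8.75 ± 1.86 to 38.5 ± 7.17% and HIPK3-202 from 41.3 ± 5.19 to 14.3 ± 2.79%. RUVBL2, an ATPase of snoRNP assembly, was the only member of the 4 splicing and 7SK lists past the threshold, with RUVBL2-201 at 0 and 7.66 ± 2.2%. No list was enriched (Fisher's exact test, lowest adjusted p = 0.721 over 24 lists). These calls did not hold: limma diffSplice called 0 genes (794 at an unadjusted p under 0.05, against 437 in edgeR), and leaving out parental replicate 1 or 2 gave 92 and 2 calls, of which 9 and 0 were among the 65, while leaving out either knockout library gave 0.

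Retained-intron transcripts held 9.72 ± 0.66% of the TPM of protein-coding genes in parental cells and 10.3 ± 0.461% in the knockout (SD, n = 2; exact permutation p = 0.667), a difference within the spread between replicates. Nonsense-mediated-decay transcripts held 2.49 ± 0.0127% and 2.78 ± 0.0449% (exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). Without the 100 genes with the highest TPM both differences changed sign, to -0.77 and -0.04 points, and as a share of reads the first was -0.12 points.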

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

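No result met the set rules for a closer look: groups of 2 libraries are too small for a test of outlying libraries, and of the 96 unmatched transcripts in the edgeR test 0 were higher and 0 lower in the knockout (4 at an unadjusted p under 0.05). The patterns below were chosen after the results were seen. So were the tests of the mitochondrial and 7SK patterns and the shuffles of gene order. The same holds for the tests of copy number, clone and the spread on chromosome 18. Set before their results were the tests of library spread, over the windows beyond the shuffles, and of GC content.

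The fall of the mitochondrially encoded mRNAs was weighed against 3 technical explanations. With library size alone the list's median was -0.69. The TMM factors lay between 0.954 and 1.045, too narrow a range to produce a fall of this size, so that outcome was known in advance. The summed reads of the 13 mRNAs and their nuclear copies changed by -0.74 on the log2 scale, which argues against reads moving to those copies. Without parental replicate 2 the median was -0.83. The longer fragments of the knockout libraries stay open as an explanation. The offset for transcript length corrects for effective length alone, and its result for this list was not weighed here. The loss of LARP7 and another trait of the clone stay open too, untested.

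The fall of 7SK RNA was weighed against reads shared with its copies and a lower recovery of short RNAs. The summed reads of 7SK and all annotated copies changed by -4.84, so a shift of reads between them does not account for it. The median of 21 other non-coding RNAs of 200 to 400 bases was -0.028, with a range from -1.14 to 0.79, which argues against a general loss of RNAs of this length. As a hypothesis, the fall may follow from the loss of LARP7, the difference the design names, which these data do not separate from the clone.

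The shifts shared by neighbouring genes went beyond chance, with 64 of 862 windows beyond the highest of 1000 shuffles. Within those windows the median absolute shift was 0.259 between knockout and parental cells and at most 0.031 between replicates of a group. The windows were picked for the first shift, which had to exceed 0.192, and not for the second. The comparison therefore cannot exclude the spread between libraries. Of the 64 windows, 59 stayed beyond the shuffles after the trend on GC content and transcript length was removed. On chromosome 18 the windows beyond the shuffles had medians of -0.259 to -0.233. Over the merged region the shift was -0.141, inside the bound of 0.192, and the parental replicates differed by 0.111. There the shift and the spread between libraries cannot be told apart. In the other 6 regions replicates differed by at most 0.048, and the region on chromosome 10 lay only just beyond the shuffles. A copy-number difference between the clone and the parental cells and regulation of whole regions cannot be told apart, since DNA was not measured and the lowest window, with 93.3% of genes lower in the knockout, was picked for its median. Loss of LARP7 and another difference of the clone cannot be told apart with 1 knockout clone, and the same holds for genes inside these regions.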

How the results depend on the processing

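All alternatives were fixed before their results; the direction of a list is that of camera and its value the median log2 change. Unless said otherwise, the cause was not tested. LARP7 passed with DESeq2 (-0.654), with no filter (-0.637) and, as a range over left-out libraries, lay between -0.819 and -0.457. Genes changed numbered 459 with DESeq2, 831 with no filter and 90 with the transcript-length offset, and 200 to 2265 with a library left out; the counts at least 2-fold were 211 with DESeq2, 427 with no filter and 186 to 720. Without a parental library the spread comes from the knockout pair alone, which was closer. All 154 genes were among the 459, the 831, the 2265 and the 1825, and 85 were among the 90.

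With the replicate number as a block, which nothing in the labels supports as a pairing, LARP7 passed (-0.64, adjusted p = 0.000525), 1656 genes changed, 496 at least 2-fold, and 0 genes changed usage (345 at an unadjusted p under 0.05), with 0 shifts. In that fit the 7SK (adjusted p = 0.0666) and histone (0.0551) lists did not pass and the epithelial and mesenchymal list did (0.0344). The difference of replicate 2 from replicate 1 correlated between the groups at 0.282 across 10605 genes, which are not independent replicates, and 2 pairs do not show a pairing.

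Of all 27 lists, 7 passed; 0 did with an estimated correlation (0 at an unadjusted p under 0.05), 0 with the directional fry test (2), and 5 to 12 with a library left out. The 12 without parental replicate 2 and the 8 without parental replicate 1 each held 6 of the 7. In fry's test of change in either direction, which does not compare a list with other genes, the 7SK and histone (adjusted p = 0.00716), interferon (0.02995) and mitochondrial (0.0339) lists passed, as did 7 lists that camera did not call (0.0155 to 0.0385). Usage changed in 122 genes with the gene-level test (99 shifts), 0 with limma diffSplice (0 shifts), 21 at a share of 10% (19) and 133 with no share minimum (79), and in 0 to 92 with a library left out (0 to 76). The retained-intron difference was -0.12 points by reads, -0.765 without the 100 genes with the highest TPM and 0.074 to 1.007 with a library left out; the nonsense-mediated-decay difference was -0.035 without those genes and 0.251 to 0.315.

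These results, none past the threshold with all libraries, changed direction. With DESeq2 and limma voom the heat shock list (0.005 and 0.028); with library size alone the U6 (0.102), tri-snRNP (0.064), LARP family (0.057) and nuclear oxidative phosphorylation (0.091) lists, CCNT2 (0.061) and CCNT1 (0.069); with no filter the U6 (0.022) and matrix (-0.039) lists; with the length offset the elongation (-0.025), LARP family (0.083), matrix (-0.047) and nuclear oxidative phosphorylation (0.037) lists, TEN1 (-0.076), COL1A1 (-0.236), LARP6 (0.107) and CCNT2 (0.277); and with protein-coding genes only the elongation (-0.031), matrix (-0.037) and heat shock (-0.015) lists turned. With a library left out, these crossed 0, as ranges over the left-out libraries: the lists of heat shock (-0.238 to 0.298, past the threshold at both ends), U6 (-0.113 to 0.14), tri-snRNP (-0.154 to 0.108), nuclear oxidative phosphorylation (-0.071 to 0.08), DNA replication (-0.195 to 0.069), hypoxia (-0.127 to 0.016), cholesterol (-0.193 to 0.079), SR proteins and hnRNPs (-0.078 to 0.171), telomerase (-0.005 to 0.159), elongation (-0.075 to 0.125), matrix (-0.103 to 0.204) and LARP family (-0.049 to 0.037), and the genes CCNT2 (-0.102 to 0.036), CCNT1 (-0.057 to 0.014), LARP6 (-0.474 to 0.186), HBA1 (-0.145 to 6.493, few reads) and HEXIM2 (-0.42 to 0.522). For markers of other cell types the median stayed between 0.065 and 0.301 while camera's direction turned.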

Other observations

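The small RNA families were chosen after their values were seen and their sums were not tested, and the test of long genes was chosen after the genes that rose had been recognised as long. Small RNA families differed between the libraries in several directions. 7SL RNA, the RNA of the signal recognition particle, was at 1597 ± 14.3 CPM in parental cells and 2195 ± 93.9 in the knockout when summed over loci, and small Cajal body RNAs were at 508 ± 69.3 and 763 ± 42. U1 was at 3571 and 10450 in the parental libraries and 2925 and 3404 in the knockout, and Y RNAs at 153 and 352 against 65.5 and 80.7, so parental replicate 2 sets much of those differences. U6, which LARP7 is known to bind during its modification, was at 5.56 ± 3.04 and 6.26 ± 0.185, a level that this library type measured with few reads.

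The hypothesis that long genes rise in the knockout came from the genes it was then tested on, so these values describe the pattern and do not test it independently. The 59 protein-coding genes that rose had a median genomic span of 193.8 kb, against 50.1 kb in random draws matched on expression and transcript length, and the highest of 10000 draws was 134.1 kb, which puts the share of draws as large at 0.01%, the smallest they can give. The 56 nuclear protein-coding genes that fell, without the 11 mitochondrial ones, had a median span of 32.9 kb, and 86.7% of matched draws were as large. The pattern may reflect the kinds of genes that differ between this clone and the parental cells as well as an effect on long genes, which cannot be told apart here with 1 clone and with a test on the genes that prompted it.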
